A study of Ceratopteris richardii with 6 samples.

How the data were processed

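Total RNA from callus of Ceratopteris richardii was isolated with CTAB, polyadenylated RNA was captured, fragmented and reverse-transcribed from random primers, and the cDNA was sequenced from both ends as 150 bp reads on a DNBSEQ instrument, per the labels' protocols. There were 3 libraries of proliferating and 3 of differentiating callus, grouped by the condition given in the labels. The deposited values are FPKM per gene and library, printed to 2 decimals, with 1 column per library and no pooling, per the file headers. The authors' FPKM divide fragments by transcript length and by mapped fragments of each library, so they are relative abundances, and no further scaling between libraries is given in the sources used here. HISAT2 2.1.0, Bowtie2 2.2.5, RSEM and DESeq2 are named, without their roles, per the submitters' processing notes. The genome build and the annotation are not given in the sources used here.

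The file held 30001 gene IDs and no gene names. Of these, 28430 matched a locus tag among the 36816 genes of the C.richardii_v2 assembly table, and the other 1571 were IDs that the authors added. That table gave 0 symbols other than the locus tags and no product descriptions, and no sequence was used here. The 40 gene lists fixed before the data were examined (hormone, meristem, cell cycle, photosynthesis, cell wall, stress and other cell type genes among them) needed descriptions or protein motifs, so 0 of them were tested. The assembly table was used only for which genes lie next to each other, and no coordinates are given because the build behind the file is not named.

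FPKM are not counts, so no count model was fitted. The number of reads per library is not known, and no counting interval can be given. The most frequent ratio of low values in proliferating 1 to those in each other library was 0.993 to 1.02. It used values from 0.3 FPKM upward in genes averaging under 3 FPKM. FPKM are already divided by the mapped fragments of each library, so unchanged genes give similar values at any depth. These ratios therefore do not measure relative depth. The share of tested genes with equal values above 0 in 2 libraries was between 0.0939% and 0.59%, so no library was a copy of another.

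Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 22371. A linear model with group as its only term was fitted to log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and two-sided moderated tests. P-values were adjusted by Benjamini and Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05 and a log2 difference of at least 1. All log2 differences are differentiating minus proliferating on this scale. Library measures (shares of the most abundant genes, genes detected) were compared by exact two-sided permutation tests in Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

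The test was checked on simulated data with 22371 genes in the same design, of which 200 were changed. The changed genes were drawn from those with a mean log2(FPKM + 1) above 3. Counted at an adjusted p under 0.05 alone, without the limit on the log2 difference, limma recovered 59.7%, 82.1% and 87.9% of genes changed by a log2 difference of 1, 2 and 3, with 11 false calls. Recovery under the full rule for a call, and among genes of lower expression, was not measured. The simulated noise was independent between genes, which the real libraries need not follow. Each gene's simulated SD was its residual SD estimated from these few libraries, and changes were assigned without regard to it. The recovery is therefore not the power to detect the real differences.

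The tests, the thresholds, the rule for named genes and the main set of alternatives were chosen before the data were examined. The rule for IDs without names allowed at most 2 genes in each direction, those with the largest difference among called genes with at least 5 FPKM in the higher group and groups that did not overlap, and the 3 most abundant genes of each group. As no gene was called, the 4 genes were taken under the same conditions without the call. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the variance model, the thresholds and leaving out each library. Library weights, the replicate number as a random effect, leaving out proliferating 2 and differentiating 3 together, and the comparison of neighbouring genes were added after seeing the data. Gene copies could share reads in the authors' quantification: 119 tested genes, in 51 sets, had the same FPKM as another gene in all 6 libraries, none of the 8 named genes among them. Copies that share only some reads cannot be seen from the values, so values of single genes are uncertain to that extent.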

Results

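Gene expression was measured by RNA sequencing in callus of the fern Ceratopteris richardii, an unorganised tissue grown in culture from which new plants can form. The 6 libraries fell into 2 groups of 3, proliferating callus and callus that had begun to differentiate, and the question was which genes differ as callus passes from proliferation to differentiation. The labels call the 3 libraries of each group biological replicates and say nothing more on whether they came from separate cultures. P-values of tests between the groups therefore rest on the spread between these libraries alone. The sample titles begin differently in the 2 groups, in a way the labels do not explain, and growth conditions are not given in the sources used here, so a difference in culture conditions cannot be told apart from the difference in state. The values covered 30001 genes, of which 23828 were above 0 in all 6 libraries. Summed FPKM (fragments scaled to transcript length and to the mapped fragments of the library) ran from 953954 to 1027755 per library, and between 2972 and 3817 genes per library were listed at 0. The number of reads behind these values is unknown, and relative depth could not be told from values already divided by mapped fragments.

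Only 3 of the 6 libraries were nearest to a library of their own group. Across the 22371 genes with a mean of at least 1 FPKM, the correlation of log2(FPKM + 1) averaged 0.956 within groups and 0.947 between them. The highest correlation of any pair was 0.981, between differentiating 3 and proliferating 1. Differentiating 3 had a correlation of 0.956 with differentiating 1 and 0.922 with differentiating 2. Proliferating 2 was nearest to differentiating 1, at 0.965, and had 0.959 with proliferating 1 and 0.954 with proliferating 3. These correlations are across genes, which are not independent replicates. The first principal component held 59.8% of the variance, and on it differentiating 3 scored -29.9, between proliferating 1 at -39.2 and proliferating 2 at 13.6.

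**Figure D1:**
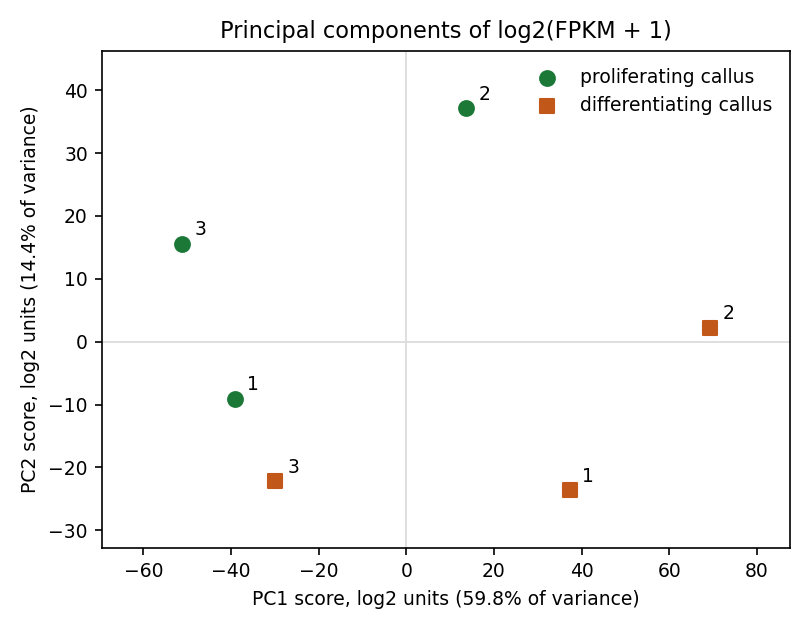
Principal component scores of the 6 libraries on log2(FPKM + 1) of the 22371 tested genes, with PC1 (59.8% of variance) on the horizontal and PC2 (14.4%) on the vertical axis, circles for proliferating and squares for differentiating callus, and the replicate number beside each point. Differentiating 1 and 2 lie at 37.3 and 69.4 on PC1 and differentiating 3 at -29.9, among the proliferating libraries on that axis. On PC2 differentiating 3 lies at -22.2, near differentiating 1 at -23.7 and outside the proliferating scores of -9.09 to 37.1. Differentiating 2, at 2.23 on PC2, lies among them.

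In differentiating callus KP509_03G023700 and KP509_05G082400 were higher by 13.0-fold and 11.4-fold, and KP509_11G015800 and BGI_novel_G001538 were lower, yet no gene passed the test between the groups. KP509_03G023700 stood at 7.23 ± 2.07 FPKM in proliferating and 93.8 ± 51.5 FPKM in differentiating callus (mean ± SD, n = 3), and KP509_05G082400 at 6.71 ± 5.83 and 76.6 ± 60.9 FPKM. KP509_11G015800 went the other way, from 170 ± 80.5 to 41.7 ± 57.8 FPKM, 4.08-fold lower. BGI_novel_G001538 was at 7.44, 7.12 and 3.06 FPKM in the proliferating libraries, and in the differentiating libraries it was listed at 0 in replicates 1 and 3 and at 1.01 FPKM in replicate 2. These were the 2 largest differences in each direction among genes whose groups did not overlap and whose higher group averaged at least 5 FPKM. On the log2(FPKM + 1) scale, which understates the change of low genes, the differences were 3.38 (SE 0.44) for KP509_03G023700, 3.26 (SE 0.70) for KP509_05G082400, -2.92 (SE 0.94) for KP509_11G015800 and -2.37 (SE 0.40) for BGI_novel_G001538, the last of which was -4.64 with a pseudocount of 0.1. For KP509_11G015800 this is larger than the ratio of the means, because the 108 FPKM of differentiating 3 weighs less in a mean of logs. Their adjusted p in limma were 0.26, 0.306, 0.337 and 0.29.

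Differentiating 3 held the differentiating value nearest to proliferating callus for 3 of these 4 genes. It had 40.7 FPKM of KP509_03G023700 where differentiating 1 and 2 had 97.2 and 144, and 25.9 FPKM of KP509_05G082400 where they had 59.8 and 144. For KP509_11G015800 it had 108 FPKM, close to the 117 FPKM of proliferating 1, while differentiating 1 and 2 had 7.45 and 9.29 FPKM. Without differentiating 3, limma gave adjusted p of 0.0234, 0.0443 and 0.0346 for KP509_03G023700, KP509_05G082400 and KP509_11G015800, and 0.0617 for BGI_novel_G001538, which did not pass. The log2 difference of KP509_11G015800 was -4.10 without differentiating 3 and -2.25 without differentiating 1, and that of KP509_05G082400 was 3.87 without differentiating 3 and 2.65 without differentiating 2. Over all 20 alternatives the limma adjusted p of KP509_03G023700, KP509_05G082400 and KP509_11G015800 ranged, in this order, from 0.00248, 0.00449 and 0.00835 up to 0.794. That of BGI_novel_G001538 ranged from 0.0323 up to 0.794 over 19 alternatives, since the filter at a mean of 5 FPKM removed it.

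**Figure D2:**
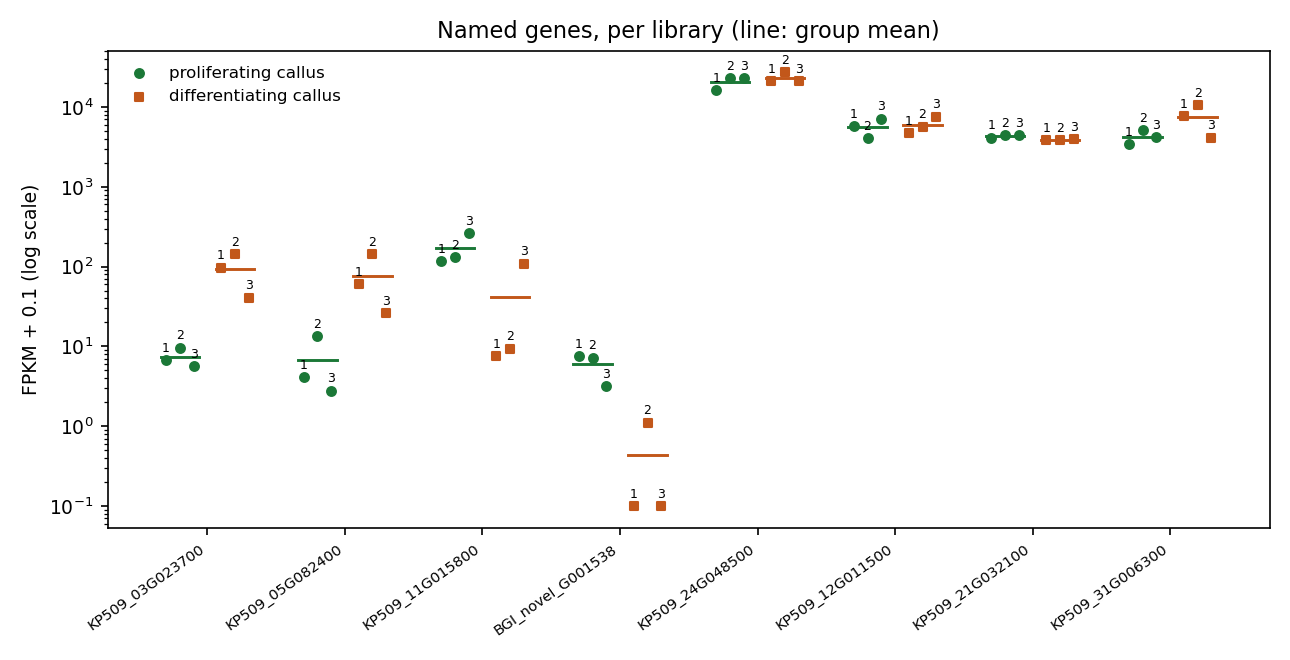
FPKM plus 0.1 on a log axis for the 8 named genes, with 1 point per library (circles for proliferating, squares for differentiating callus), its replicate number above it and a line at the mean of each group. The 4 genes on the left have groups that do not overlap, and in 3 of them differentiating 3 lies nearest to the proliferating libraries.

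Across the transcriptome, 449 genes were at least 2-fold higher and 329 at least 2-fold lower in differentiating callus. In 172 of the higher and 129 of the lower genes the 3 libraries of one group all lay above the 3 of the other. These 301 genes became 1379 without differentiating 3, 869 without proliferating 2 and 458 with a pseudocount of 0.1, and groups of fewer libraries are more often apart by chance. Irrespective of size, 1751 genes had all differentiating libraries above the proliferating ones and 2077 had them below, together 17.1% of tested genes, where chance gives 10% on average over splits. The 3828 genes compare with 860 to 5802 in the other 9 splits of the 6 libraries, the highest with proliferating 1, proliferating 3 and differentiating 3 against the rest. The median log2 difference over all tested genes was -0.0011 and the median SE was 0.17. With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05 and at least 2-fold, and the smallest adjusted p was 0.234. At an unadjusted p under 0.05 in limma there were 2843 genes, 1237 higher and 1606 lower, where 1119 would be counted on average with no effect. The other 9 splits gave 266 to 4558 such genes, so a count above 1119 is not by itself due to the groups. Without differentiating 3 limma called 337 genes, 131 higher and 206 lower, and counted 4596 at an unadjusted p under 0.05. That last count was 1587, 1300 and 1650 without proliferating 3, differentiating 1 and differentiating 2.

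**Figure D3:**
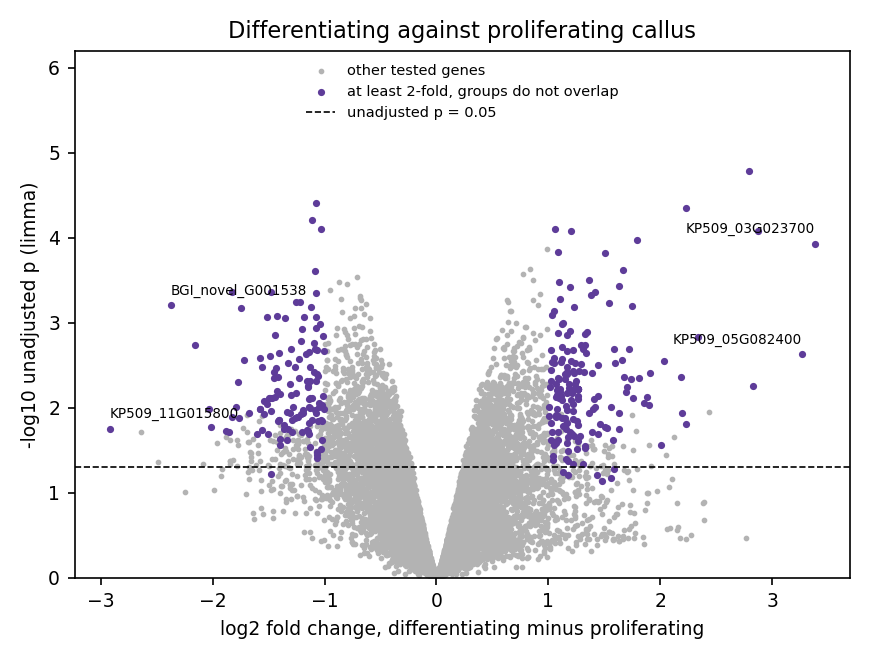
Log2 fold change of each of the 22371 tested genes on log2(FPKM + 1), differentiating minus proliferating, against -log10 of the unadjusted limma p, with a dashed line at the 0.05 level. The 301 genes in purple differed at least 2-fold with groups that did not overlap, and no gene reached an adjusted p under 0.05.

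Of 9124 genes averaging 1 to 10 FPKM, 232 were higher and 137 lower by at least 2-fold in differentiating callus. Among 11527 genes at 10 to 100 FPKM these counts were 172 and 145, and among 1720 genes at 100 FPKM or more they were 45 and 47. The share of genes at an unadjusted limma p under 0.05 was 9.57%, 14.5% and 17.2% in these classes. Gene models that the authors added under their own IDs differed by at least 2-fold in 11.4% of 1162 cases, 83 higher and 49 lower, against 5.76% of 1059 genes on unplaced sequences, 38 higher and 23 lower, and 2.90% of the 20150 genes placed on chromosomes. The added models had a median of 4.34 FPKM, against 8.98 FPKM for the unplaced and 14.6 FPKM for the chromosomal genes. They had a median SE of 0.27 against 0.17 for the chromosomal genes, and the share at an unadjusted limma p under 0.05 was 12.5% for the added models, 12.4% for the unplaced and 12.7% for the chromosomal genes. Groups did not overlap in 7 of the 83 and 23 of the 49 added models. No difference between these classes was tested.

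The same gene, KP509_24G048500, was the most abundant in all 6 libraries and took between 1.72% and 2.63% of summed FPKM. It averaged 20758 ± 3797 FPKM in proliferating and 22959 ± 3559 FPKM in differentiating callus (mean ± SD, n = 3), a log2 difference of 0.15 with a limma adjusted p of 0.84. KP509_12G011500 had 5628 ± 1512 and 5972 ± 1432 FPKM. The log2 difference of KP509_12G011500 was 0.10, and it turned to -0.12 without proliferating 2, -0.09 without differentiating 3 and -0.13 after quantile normalization. KP509_24G048500 turned to -0.010 without proliferating 1, and was 0.03 without differentiating 2 and 0.24 without proliferating 3. KP509_21G032100 had 4319 ± 185 FPKM in proliferating and 3905 ± 61.4 FPKM in differentiating callus, with groups that did not overlap, a log2 difference of -0.14 and a limma adjusted p of 0.727. KP509_31G006300 averaged 4256 ± 887 and 7408 ± 3183 FPKM, a log2 difference of 0.72 (SE 0.37) with a limma adjusted p of 0.453, and its 4125 FPKM in differentiating 3 lay within the proliferating range. The log2 difference of KP509_31G006300 was 0.42 without differentiating 2, 1.09 without differentiating 3 and 0.38 after quantile normalization. It was 1.24 with a limma adjusted p of 0.045 when proliferating 2 and differentiating 3 were both left out, a fit added after the data were seen, and over all 20 alternatives the adjusted p ran from 0.045 to 0.824.

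The 10 most abundant genes took 6.43% ± 0.319 of summed FPKM in differentiating and 5.85% ± 0.336 in proliferating callus (mean ± SD, n = 3; exact two-sided permutation p = 0.2, Benjamini-Hochberg adjusted 0.6 over 6 measures). For the 100 most abundant genes the shares were 19.9% ± 0.644 and 19.3% ± 0.918 (exact permutation p = 0.5, adjusted 0.7). Gene models added by the authors took 1.87% ± 0.122 in differentiating and 2.04% ± 0.125 in proliferating callus (exact permutation p = 0.2, adjusted 0.6). Genes at 1 FPKM or more numbered 22251 ± 360 and 22001 ± 311 (exact permutation p = 0.5, adjusted 0.7). The other 2 measures, the share of the single most abundant gene and the number of genes listed at 0, gave exact permutation p of 0.6 and 0.7. With 3 libraries against 3 the exact test cannot go below 0.1.

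Only 3 genes had at least 1 FPKM in every library of one group and under 0.1 FPKM in every library of the other, and they are named here after their values were seen. KP509_05G028200 had 1.37, 1.44 and 5.43 FPKM in the differentiating libraries, and KP509_29G080200 had 2.27, 1.18 and 1.12 FPKM. Both were listed at 0 in the 3 proliferating libraries. BGI_novel_G001034 had 3.79, 1.79 and 1.82 FPKM in the proliferating libraries and was listed at 0 in the 3 differentiating ones. With 1 library left out in turn the count was 10, 7 and 7 without proliferating 1, 2 and 3, and 13, 6 and 17 without differentiating 1, 2 and 3, since fewer libraries had to meet the limits.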

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

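Library weights, the random effect and leaving out proliferating 2 and differentiating 3 together were chosen only after the results were seen. Of 20 alternatives to the limma comparison, 16 gave 0 called genes. Among these, dropping the fold change threshold and requiring an adjusted p under 0.01 reused the main fit. Its smallest limma adjusted p was 0.234, so their 0 was fixed in advance. The replicate block called 112 genes, array weights 623 and leaving out both libraries 1329. The fits that left out 1 library called 0 to 337. Both libraries were dropped for standing apart, which by construction narrows the spread, and the weights rested on differentiating 1 (8.67, others 0.465 to 0.906). Genes at an unadjusted limma p under 0.05 numbered 1300 to 4596 with 1 library left out, against 2843, and 6955 and 5580 with array weights and with both left out. Genes in one group only numbered 6 to 17 with 1 library left out, against 3. The log2 difference of KP509_12G011500 turned to -0.13 (quantile normalization), -0.16 (array weights) and -0.30 (both left out), and ran from -0.12 to 0.28 with 1 library left out. With 1 library left out that of KP509_24G048500 ran from -0.010 to 0.24. Beyond fewer libraries, the cause was not tested.

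Whether the replicate numbers pair the libraries was not settled: deviations of same-numbered libraries had r of -0.0955, 0.572 and 0.45. Differently numbered ones had r of -0.635 to 0.343. Libraries numbered 2 and 3 were closest to their own number, and those numbered 1 were not. The 112 genes of the replicate block (57 higher, 55 lower) are therefore a value only. The mean correlation within groups exceeded that between groups by 0.00895. This was 0.00784 with a pseudocount of 0.1 and 0.00938 with Spearman correlation. The SD of the correlations within groups, 0.0187, was larger than the difference itself, and no library was left out for this measure. With 1 library left out, the difference between groups in the share of the 10 most abundant genes ran from 0.415 to 0.776 percentage points, against 0.585, and that of the 100 most abundant from 0.24 to 1.13, against 0.602. The 40 gene lists were not run under any setting. Absolute depth is unknown.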

Other observations

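Tests on neighbouring genes without overlapping models and without genes of identical values, on abundant genes and on stages were set before their results were seen, and the other tests here were chosen only after the results were seen.

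Some of the genes with large differences between the groups had a neighbour with a large difference in the same direction, although no gene passed the test. The next gene after KP509_03G023700 in the C.richardii_v2 order, KP509_03G023800, had 7.69 ± 2.68 FPKM in proliferating and 63.9 ± 23.6 FPKM in differentiating callus (mean ± SD, n = 3), 8.31-fold higher with a log2 difference of 2.88 and a limma adjusted p of 0.234. The gene 2 places after KP509_05G082400, KP509_05G082600, had 53.2 ± 9.80 and 386 ± 134 FPKM, 7.25-fold higher, with a log2 difference of 2.79 (SE 0.27) and the same limma adjusted p of 0.234. The gene between them, KP509_05G082500, differed by 0.40 on the log2 scale (1.36-fold higher), and KP509_05G082200, 2 places before KP509_05G082400, was lower, at 144 ± 34.5 and 71.9 ± 19.4 FPKM (log2 difference -0.99, limma adjusted p 0.306). The gene before KP509_11G015800, KP509_11G015700, averaged 79.0 ± 36.2 and 22.4 ± 20.5 FPKM, 3.53-fold lower with a limma adjusted p of 0.311. KP509_03G023600, the gene before KP509_03G023700, differed by 2.05 on the log2 scale. It had 0.22 FPKM in differentiating 3, near its proliferating mean of 0.147 FPKM. The remaining tested neighbours within 2 places differed less: KP509_03G023500 by 0.12, KP509_11G015600 by -0.34, KP509_11G015900 by -0.71 and KP509_11G016000 by -0.38. These neighbours are named after their values were seen.

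Over 13527 pairs of adjacent tested genes the log2 differences had a Pearson r of 0.168 and a Spearman rho of 0.0975, across pairs that are not independent replicates. In 1000 random gene orders r lay between -0.0281 and 0.0255, so neighbour order was related to the differences (permutation p = 0.001, the smallest these orders can give). Both genes differed at least 2-fold in the same direction in 59 pairs (30 higher, 29 lower) and in opposite directions in 3, where random orders gave 5.78 same-direction pairs on average and at most 15. Reads shared by overlapping models and by copies with identical values are argued against as its source, since r was 0.168 without the 180 overlapping pairs and 0.166 without the 119 genes whose values equalled another gene's in all 6 libraries. Other splits of the 6 libraries gave r of 0.0809 to 0.168, the highest of them as large as that of the labelled groups, so the correlation was not specific to the groups, reads shared in part by copies with unequal values stay open, and no biological explanation was tested.

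Differentiating 3 lay nearer to proliferating 1 and 3 than to differentiating 1 and 2, and proliferating 2 lay nearest to differentiating 1. Sampling noise of weakly expressed genes is argued against: among 1720 genes averaging at least 100 FPKM, the correlation of differentiating 3 with proliferating 1 exceeded that with differentiating 1 by 0.0813 (95% bootstrap interval over genes 0.0594 to 0.109). Genes are not independent replicates, and this interval holds no spread between libraries. A swap of these 2 libraries stays open: the labelled split had 301 genes at least 2-fold apart with no overlap, against at most 124 in the 8 splits mixed in the same way, but the highest of so few splits cannot exclude a swap, and the split with these 2 libraries exchanged had 1036. Whether differentiating 3 could be the fourth proliferating library cannot be told apart from a true label either, since 1 of the 3 proliferating libraries put in its place gave as many genes (1036 for proliferating 2, 124 and 66 for proliferating 1 and 3). Libraries at different stages of differentiation may also account for it: on genes ranked without both libraries, differentiating 3 lay 0.221 of the way from proliferating to differentiating callus (quartiles 0.0649 and 0.367) and proliferating 2 lay 0.407 of the way (0.291 and 0.674), which left this undecided. With each library left out alone, proliferating 1 lay at 0.375 (0.0899 and 0.644), proliferating 2 at 0.432 and proliferating 3 at 0.0514. Differentiating 1, 2 and 3 lay at 1.01, 0.979 and 0.258. Proliferating 1 also took an intermediate position here, but each library was placed between other reference libraries, on its own 400 genes of smallest limma p. For proliferating 1 the differentiating reference included differentiating 3, its nearest library. No baseline for such positions was measured, so they cannot tell which libraries are intermediate.

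The labelled groups gave 2843 genes at an unadjusted limma p under 0.05 and 0 called genes. The highest of the other 9 splits of the 6 libraries gave 4558, and 2 of the 10 splits gave at least as many as the labelled one, itself included, but 10 splits are too few for a share under 0.05. That highest split set proliferating 1, proliferating 3 and differentiating 3 against the rest, called 359 genes and held 52.2% of the variance, against 28.6% for the labelled groups, which restates the structure seen in the correlations, one that the labels follow only in part. Apart from that split and the labelled one, the splits gave at most 969 genes at an unadjusted limma p under 0.05 and 22.8% of the variance.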
